A study of Mus musculus with 9 samples.

How the data were processed

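Gene expression was measured in TAMH cells, a mouse hepatocyte line, on 9 Affymetrix Mouse Gene 2.1 ST arrays, 3 each for cells in medium alone, cells given diquat at 18 µM and cells given paraquat at 126 µM, all for 9 h. Per the labels' protocols, total RNA was isolated with an organic extraction followed by a purification column and labelled with biotin. Groups and replicate numbers were taken from the sample titles. The descriptions of diquat and paraquat replicates 2 and 3 give the number 1 instead, so the numbers behind the replicate block are uncertain for these arrays. The labels describe 3 dishes per treatment and do not say whether these were separate cultures, so p-values measure the spread between these samples, which may be technical.

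The deposited values are on a log2 scale. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.1 and RMA, a method that corrects background, normalizes arrays by quantiles and summarizes probes. Its settings are not given in the sources used here. The deposited table held 34472 features with values from 3.89 to 13.19, rounded to 2 decimals. Array medians lay between 5.95 and 6.04. Scanner files and detection calls were not used here, so a value near the bottom of the range cannot be separated from background, and the number of arrays limits the precision.

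Features were named from the platform annotation: 23521 carried 1 gene symbol, 1814 carried several and 9137 carried none. Of those with 1 symbol, 23328 were matched by Entrez identifier to the RefSeq gene table of the mouse assembly GRCm38.p6, and no symbol of a gene tested changed. Genes were named only from features with 1 symbol. Where a gene had several features (1082 genes), the feature with the highest mean over the 9 arrays was kept, which left 22180 genes. No coordinates are given because the build behind the array annotation is not given in the sources used here.

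The deposited log2 values were fitted without further normalization in limma 3.58.1 (R 4.3.3), with lmFit and eBayes, 1 mean per group and no covariates. All 9 arrays entered 1 fit, so the 3 groups shared 1 estimate of the spread. The contrasts were diquat minus control, paraquat minus control and paraquat minus diquat. Adjusted p-values are those of limma with Benjamini-Hochberg adjustment over the 22180 genes, with a threshold of 0.05, and a second count also required a change of at least 2-fold. Errors beside fold changes are limma's standard errors, and errors beside levels are standard deviations over 3 arrays. Intervals are 95% intervals from the same fit.

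Sets were tested with limma's camera over 35 gene lists with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data. Of the 834 list entries, 759 had a feature of their own and the other 75 were not analysed here. Each array's list score is the mean, over a list's genes, of the log2 difference from the control mean. The tests, the lists, the settings to be varied and the rule for naming genes were fixed before the data were examined. The rule took, for each contrast, the 12 highest and 12 lowest log2 fold changes among genes past the adjusted p whose 3 arrays of one group all lay on the same side of the 3 of the other, without gene models, small RNAs and certain gene families. It added up to 4 members of each described list that passed with the largest absolute change, or the top 2 if none passed, and 21 fixed genes, of which 18 were measured. Genes named outside this rule are said to have been chosen after their values were seen.

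Because both compounds were set against the same controls, 100 data sets with unchanged groups were simulated to give the overlap and correlation that shared controls produce with no effect. Alternatives covered the replicate number as a block, an intensity trend with a robust prior, a filter on dim genes, centring and quantile normalization of the arrays, a fit of the 2 groups compared, the mean of a gene's features, all features, array weights, a test against a fold of 1.2 and leaving out each array. A fit on protein-coding genes was added after the data were seen.

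The fit was tested on simulated data made from the real means of the 22180 genes and limma's moderated spreads, which are pulled toward a common value. The noise was drawn independently for each gene and array, so correlation between genes was left out. For diquat against control, 82.1% of 67 genes changed by 0.3 on the log2 scale were recovered, 98.5% of 67 changed by 0.5 and 100% of 66 changed by 1, and 7 unchanged genes were called. For paraquat against control the shares were 86.6%, 97% and 100%, with 11 unchanged genes called, and for paraquat against diquat 85.1%, 98.5% and 100%, with 7. Each simulated contrast held many changed genes at once, which eases the adjusted threshold. In the real data 0 genes passed between the compounds, so the share recovered at 0.3 does not carry over to that contrast. Figures were drawn with matplotlib 3.10.9.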

Results

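Expression was profiled in TAMH cells after 9 h in medium alone, with diquat at 18 µM or with paraquat at 126 µM. Both herbicides are viologens, bipyridylium salts that cycle between oxidized and reduced forms in cells and generate superoxide. Each group held 3 arrays, and 22180 genes were tested. No 2 arrays held identical values, and Pearson correlations between arrays across genes lay between 0.9952 and 0.9991. The first principal component, with 40.2% of the variance, separated the control arrays from the treated ones. The second, with 20.8%, set diquat replicate 3 apart from the other arrays: its root-mean-square difference from the mean of its group mates was 0.134 on the log2 scale, against 0.0714 to 0.115 for the other arrays.

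The first comparison asked what diquat changed. The largest rise among genes named by rule was in Slc7a11, the cystine importer that feeds glutathione synthesis, from 7.65 ± 0.18 to 10.27 ± 0.07 (SD, n = 3 each), a 6.15-fold change. Ptgs2, the inducible cyclooxygenase, rose 4.89-fold from 6.41 ± 0.13 to 8.70 ± 0.13 (SD, n = 3 each). The other rises among the 12 largest included Stc1 2.74-fold, the urokinase receptor gene Plaur 2.63-fold, the collagenase Mmp13 2.58-fold, Csf2 2.56-fold, Adm2 2.42-fold and the chemokine Cxcl2 2.32-fold. The EGF receptor ligands Btc and Ereg rose 2.33-fold and 2.12-fold, the transcription factor Creb5 2.30-fold and the transferrin receptor Tfrc 2.13-fold. The falls included the amino acid transporter Slc38a4 (2.36-fold), the hepatic glucose transporter Slc2a2 (2.33-fold), the thioredoxin-interacting protein gene Txnip (2.21-fold) and the liver transcription factor Onecut1 (2.15-fold). Smaller falls were seen for Hpgd (1.91-fold), Slc16a12 (1.90-fold), Sgpp2 (1.85-fold), Mme (1.75-fold), A1cf (1.69-fold), Spatc1l (1.67-fold), Palmd (1.66-fold) and Slc6a13 (1.64-fold).

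In all, 1558 genes passed limma's adjusted p for diquat against control, 917 higher and 641 lower, of which 22 changed at least 2-fold (18 higher, 4 lower). The balance of higher and lower calls moved with scaling: 58.9% of calls were higher as deposited, 77.5% after centring each array on its median and 45.2% after quantile normalization. The count was 887, 802 and 1000 without control replicate 1, 2 or 3, 959 when the paraquat arrays were left out of the fit, and 117 when tested against a fold of 1.2.

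Targets of ATF4, the transcription factor of the integrated stress response, moved as a group under diquat. Of 29 measured, 24 rose and none fell (25 and 0 adjusted over the list alone), among them the glutathione-degrading enzyme gene Chac1 (2.05-fold), Atf3 (1.90-fold), Sesn2 (1.78-fold), Trib3 (1.77-fold) and Ddit3 (1.74-fold), which encodes CHOP. Of 34 immediate early and MAPK feedback genes, 20 rose and 0 fell (23 and 2 adjusted over the list alone), including Ier3 (1.84-fold), the phosphatases Dusp5 (1.77-fold) and Dusp4 (1.76-fold), and Egr1 (1.60-fold). These 2 lists passed limma's camera with the preset correlation (adjusted p = 1.68e-35 and 1.94e-17) and with an estimated correlation (adjusted p = 0.00178 and 0.0437).

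Diquat also raised 9 of 28 NRF2 targets and lowered 0 (13 and 1 adjusted over the list alone). They included Slc7a11, the heme oxygenase Hmox1 (1.64-fold), Abcc4 (1.48-fold) and the thioredoxin reductase Txnrd1 (1.33-fold). Other fixed NRF2 targets did not pass: Nqo1 lay near the bottom of the range at 5.46 in controls and 5.42 under diquat, the log2 change of Gclm was 0.00 ± 0.04 (SE), and that of Srxn1 was 0.19 ± 0.05 (SE) at an adjusted p of 0.0514 in limma. Srxn1 passed under 6 alternatives, among them the fit without diquat replicate 3 (log2 change 0.25, adjusted p = 0.00746). The list passed camera in the upward direction (adjusted p = 1.02e-09), and its call was lost with an estimated correlation (adjusted p = 0.0646). Of 27 antioxidant enzyme genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), with no call for the list (adjusted p = 0.47; downward at 0.0369 after quantile normalization), and Sod1, Sod2 and Cat changed by 0.08, 0.03 and -0.10 on the log2 scale, none past the test. The antioxidant list also holds Txnip, which encodes a thioredoxin-interacting protein and not an enzyme, and its fall is among the 3 counted. Of 7 metallothionein and zinc genes, 0 passed.

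Of 29 p53 targets, 8 rose and 0 fell under diquat (11 and 0 adjusted over the list alone), among them the kinase genes Plk3 (1.90-fold) and Plk2 (1.35-fold), Mdm2 (1.30-fold) and the cell cycle inhibitor Cdkn1a (1.28-fold). Of 24 hypoxia and glycolysis genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), including Vegfa (1.73-fold), Ndrg1 (1.69-fold) and the hexokinase Hk2 (1.33-fold). Of 28 NF-kB and inflammatory genes, 9 rose and 1 fell (13 and 3 adjusted over the list alone), and Cxcl1 and Cxcl10 rose 1.36-fold and 1.35-fold. Ribosome biogenesis genes rose in 9 of 27 cases and fell in 0 (14 and 0 adjusted over the list alone), with Wdr43 higher by 0.26 and Nop2 by 0.23 on the log2 scale. These 4 lists passed camera upward (adjusted p = 2.97e-10, 1.41e-07, 1.01e-07 and 6.13e-12), and each call was lost with an estimated correlation (adjusted p = 0.103, 0.155, 0.103 and 0.102).

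Some members of 5 lists of liver, fatty acid and cell cycle genes fell with diquat. Of 31 hepatocyte markers, 10 fell and 0 rose (15 and 1 adjusted over the list alone), including the urea cycle gene Cps1 (1.68-fold), the fibrinogen gene Fga (1.47-fold) and G6pc (1.43-fold). Albumin, Alb, stood at 12.73 in both groups, close to the top of the array's range. Fatty acid oxidation genes fell in 8 of 26 cases and rose in 1 (15 and 1 adjusted over the list alone), with Ppara 1.19-fold lower, and fatty acid synthesis genes fell in 6 of 16 and rose in 0 (6 and 0 adjusted over the list alone), with Pnpla3 1.44-fold lower. Of 30 S phase genes 5 fell and 0 rose (12 and 0 adjusted over the list alone), with Ccne1 1.24-fold lower, and of 27 mitosis genes 4 fell and 0 rose (6 and 0 adjusted over the list alone), with a log2 change of -0.27 for Mki67. These 5 lists passed camera downward (adjusted p = 6.55e-07, 3.4e-05, 4.33e-05, 4.32e-06 and 0.000131), and each call was lost with an estimated correlation (adjusted p = 0.181, 0.103, 0.103, 0.351 and 0.429).

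Camera called 17 of the 35 lists for diquat with the preset correlation, 12 up and 5 down, and 2 with an estimated correlation. In the 9 other splits of these 6 arrays, which mix the groups 2 to 1 on each side and so keep part of the treatment difference, the preset setting called between 4 and 15 lists and the estimated setting 0. The remaining upward calls were the interferon-stimulated (4 of 22 higher), autophagy and lysosome (5 of 33 higher, 1 lower), EGF receptor ligand and receptor (4 of 11 higher, 1 lower), YAP, SRF and matrix-response (7 of 20 higher, 2 lower) and mitochondrially encoded lists (0 of 10 past the test). Adjusted over the list alone, 7, 8, 4, 9 and 0 of their members were higher and 0, 2, 3, 2 and 0 lower. Each call was lost with an estimated correlation (adjusted p = 0.328, 0.328, 0.328, 0.155 and 0.498). The EGF receptor call was also lost without control replicate 3 (adjusted p = 0.0732) or diquat replicate 3 (0.145) or with array weights (0.0774), the mitochondrially encoded call without diquat replicate 3 (0.0933), and the autophagy call after quantile normalization (0.0577). Genes of the nuclear-encoded respiratory chain (0 of 33 higher, 2 lower; adjusted p = 0.47, and 0.015 downward after quantile normalization) and of viologen reduction and transport (1 of 13 higher, 0 lower; adjusted p = 0.748) were not called. Median, mean and test differed in sign for the heat shock list (median -0.01, test up), the circadian list (median -0.01, test up), the DNA repair list (mean -0.02, test up), and the lists of iron handling and viologen reduction (medians -0.02 and -0.04, means and tests up), none of them called.

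**Figure D1:**
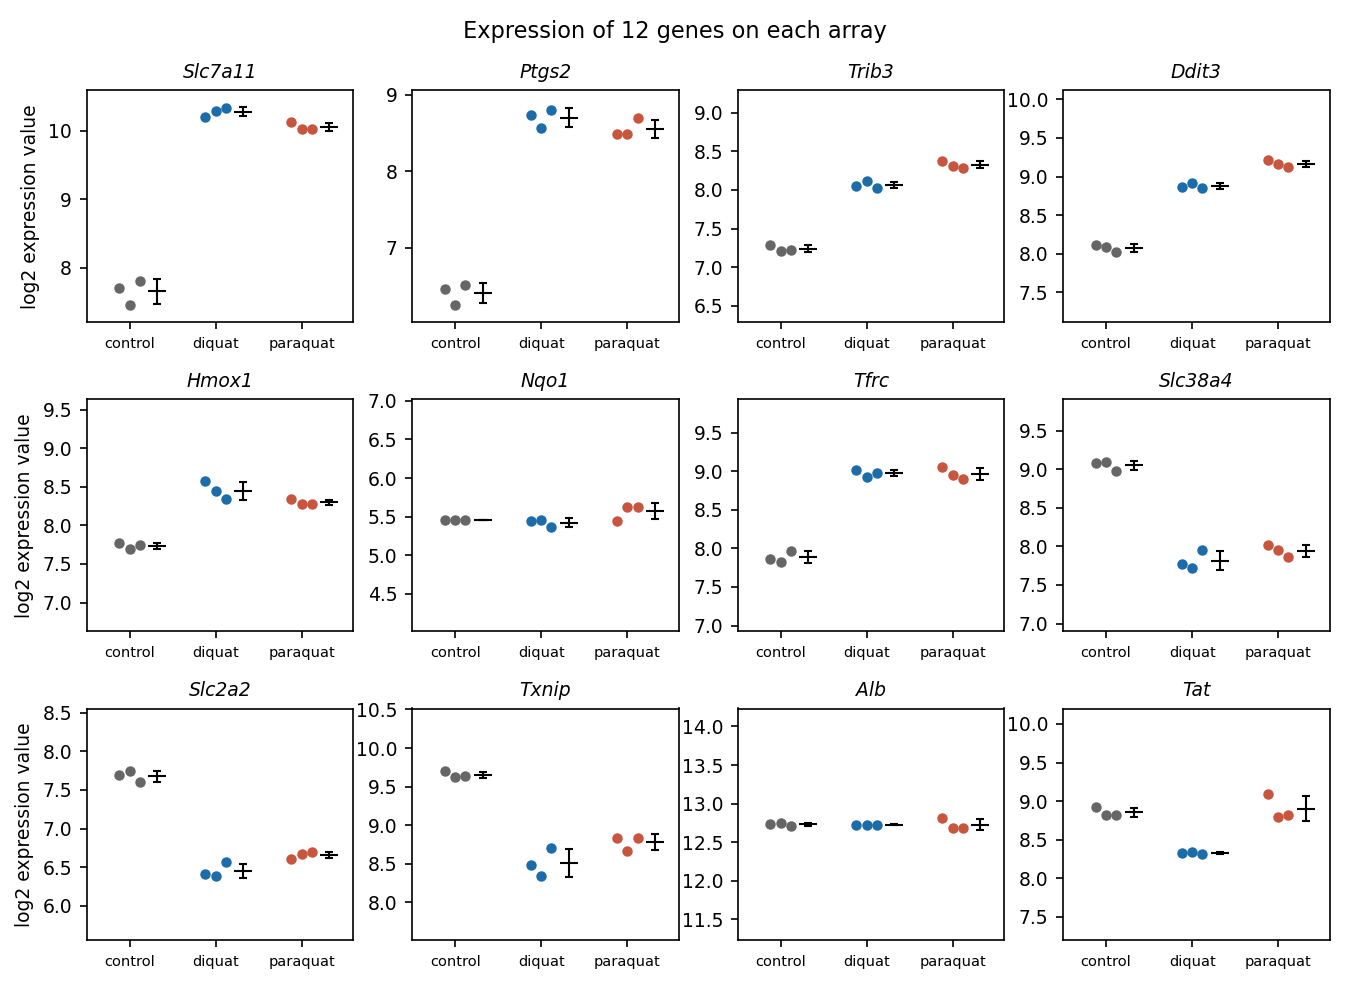
Log2 expression values of 12 genes on each array, with groups on the horizontal axis. Points are arrays, and the black bar and whiskers beside them are the mean and SD of 3 arrays. Slc7a11 rose from a mean of 7.65 in controls to 10.27 with diquat and 10.05 with paraquat, and Tat was lower with diquat (8.33) than with paraquat (8.90).

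The second comparison asked what paraquat changed. Slc7a11 rose 5.28-fold to 10.05 ± 0.06 (SD, n = 3) and Ptgs2 rose 4.42-fold to 8.55 ± 0.12 (SD, n = 3). Adm2 rose 2.68-fold, Plaur 2.51-fold, Stc1 2.47-fold, the retinol dehydrogenase Dhrs9 2.32-fold, Creb5 2.30-fold, Cxcl2 2.20-fold and Csf2 2.19-fold. The ATF4 targets Chac1 (2.25-fold), Atf3 (2.22-fold) and Ddit3 (2.13-fold) stood among the 12 largest rises named by rule. Falls were seen for Slc38a4 (2.15-fold), Onecut1 (2.14-fold), Slc16a12 (2.14-fold), Slc2a2 (2.03-fold), A1cf (1.87-fold), Txnip (1.83-fold), Hpgd (1.82-fold), Crp (1.81-fold), the iron exporter Slc40a1 (1.77-fold), Spatc1l (1.76-fold), Sgpp2 (1.67-fold) and Id2 (1.65-fold).

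For paraquat against control, 1014 genes passed limma's adjusted p, 517 higher and 497 lower, and 24 of them changed at least 2-fold (20 higher, 4 lower). The balance moved with the setting: 51% of calls were higher as deposited, 55% after centring, 43.9% after quantile normalization (557 higher, 713 lower), 45.9% with array weights (745 and 878), 62.6% and 57.1% without control replicate 1 or 2, and 45%, 60.7% and 58.9% without paraquat replicate 1, 2 or 3. The count was 596 and 574 without control replicate 1 or 2, 575 and 574 without paraquat replicate 2 or 3, and 95 when tested against a fold of 1.2. With array quality weights it was 1623.

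ATF4 targets rose in 24 of 29 cases under paraquat and fell in 0 (25 and 0 adjusted over the list alone), with Trib3 2.12-fold higher. Of the immediate early and MAPK feedback genes, 17 of 34 rose and 0 fell (19 and 1 adjusted over the list alone), among them Dusp4 (1.84-fold), Dusp5 (1.83-fold), Ier3 (1.57-fold) and Nr4a1 (1.57-fold). Both lists passed camera with the preset (adjusted p = 1.22e-47 and 1.14e-18) and with an estimated correlation (adjusted p = 0.000759 and 0.0368).

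NRF2 targets rose in 7 of 28 cases and fell in 0 (9 and 0 adjusted over the list alone), including Hmox1 (1.48-fold), Abcc4 (1.38-fold), Osgin1 (1.33-fold) and Txnrd1 (1.16-fold), while Nqo1, Gclm and Srxn1 changed by 0.11, -0.10 and 0.07 on the log2 scale and did not pass. Of the p53 targets 6 of 29 rose and 0 fell (6 and 1 adjusted over the list alone), with Plk3 1.88-fold and Cdkn1a 1.23-fold higher. NF-kB and inflammatory genes rose in 6 of 28 and fell in 1 (9 and 2 adjusted over the list alone), with Cxcl10 1.36-fold higher. Ribosome biogenesis genes rose in 6 of 27 and fell in 0 (17 and 0 adjusted over the list alone), with Nop2 1.19-fold higher. These 4 lists passed camera upward (adjusted p = 0.000116, 0.00393, 1.24e-06 and 7.96e-15), and each call was lost with an estimated correlation (adjusted p = 0.17, 0.419, 0.136 and 0.0735). The hypoxia list (5 of 24 higher, 0 lower) was not called (adjusted p = 0.0742), while Vegfa and Ndrg1 both rose 1.61-fold. It passed upward without control replicate 1 (adjusted p = 0.0208) or paraquat replicate 2 or 3 (0.0188 and 0.0255).

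Hepatocyte markers fell in 9 of 31 cases under paraquat and rose in 0 (14 and 0 adjusted over the list alone), with Cps1 1.75-fold and Fga 1.58-fold lower. Fatty acid oxidation genes fell in 8 of 26 and rose in 1 (14 and 3 adjusted over the list alone), with Eci2 1.32-fold lower, and fatty acid synthesis genes fell in 4 of 16 and rose in 0 (6 and 0 adjusted over the list alone), with Gpam 1.27-fold lower. S phase genes fell in 7 of 30 (15 adjusted over the list alone), with Ccne1 1.25-fold lower, and mitosis genes in 2 of 27 (2 adjusted over the list alone), with Mki67 1.21-fold lower. These 5 lists passed camera downward (adjusted p = 1.79e-07, 3.17e-06, 7.44e-07, 3.14e-12 and 1.23e-06), and each call was lost with an estimated correlation (adjusted p = 0.191, 0.0984, 0.0735, 0.191 and 0.283). Endoplasmic reticulum chaperones (1 of 21 higher, 2 lower) and antioxidant enzymes (0 of 27 higher, 2 lower) were also called downward (adjusted p = 0.000906 and 0.00251), with 1 higher and 4 lower and 1 higher and 3 lower adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.315 and 0.213). The falls counted for the antioxidant list again include Txnip, which does not encode an enzyme, and the list was not tested without it. With diquat the endoplasmic reticulum list had 1 higher and 3 lower (1 and 3 adjusted over the list alone) and was not called (adjusted p = 0.0601). It passed downward with diquat in 7 of 19 alternatives, among them without control replicate 2 (0.0363) or diquat replicate 3 (0.00571) and after quantile normalization (0.00119), and it was not called between the compounds (0.511). Hspa5, the chaperone BiP, changed by 0.04 ± 0.03 on the log2 scale (SE) and did not pass.

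Camera called 17 of 35 lists for paraquat with the preset correlation, 10 up and 7 down, and 2 with an estimated correlation. In the 9 other splits of these 6 arrays, which again keep part of the treatment difference, the preset setting called between 3 and 17 lists and the estimated setting 0. The remaining upward calls were the mitochondrially encoded (0 of 10 past the test), autophagy and lysosome (4 of 33 higher), EGF receptor (3 of 11 higher, 1 lower) and YAP, SRF and matrix-response lists (6 of 20 higher). Adjusted over the list alone, 0, 5, 4 and 6 of their members were higher and 0, 0, 2 and 2 lower. Each call was lost with an estimated correlation (adjusted p = 0.451, 0.451, 0.283 and 0.251). Without control replicate 3 or paraquat replicate 1, the autophagy call (adjusted p = 0.0762 and 0.154) and the EGF receptor call (0.063 and 0.0545) were also lost, the latter also with the 2 groups alone (0.076). The nuclear-encoded respiratory chain (0 of 33 past the test, adjusted p = 0.0882, and downward at 0.0287 after quantile normalization, 0.0319 with all features and 0.0384 without paraquat replicate 1) and viologen reduction lists (1 of 13 higher, 0 lower; adjusted p = 0.434) were not called. Median and test differed in sign for the metallothionein list (median -0.02), the viologen list (-0.01), the cholangiocyte list (-0.01) and, with a mean of 0.00 and a test downward, the iron list, none of them called.

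**Figure D2:**
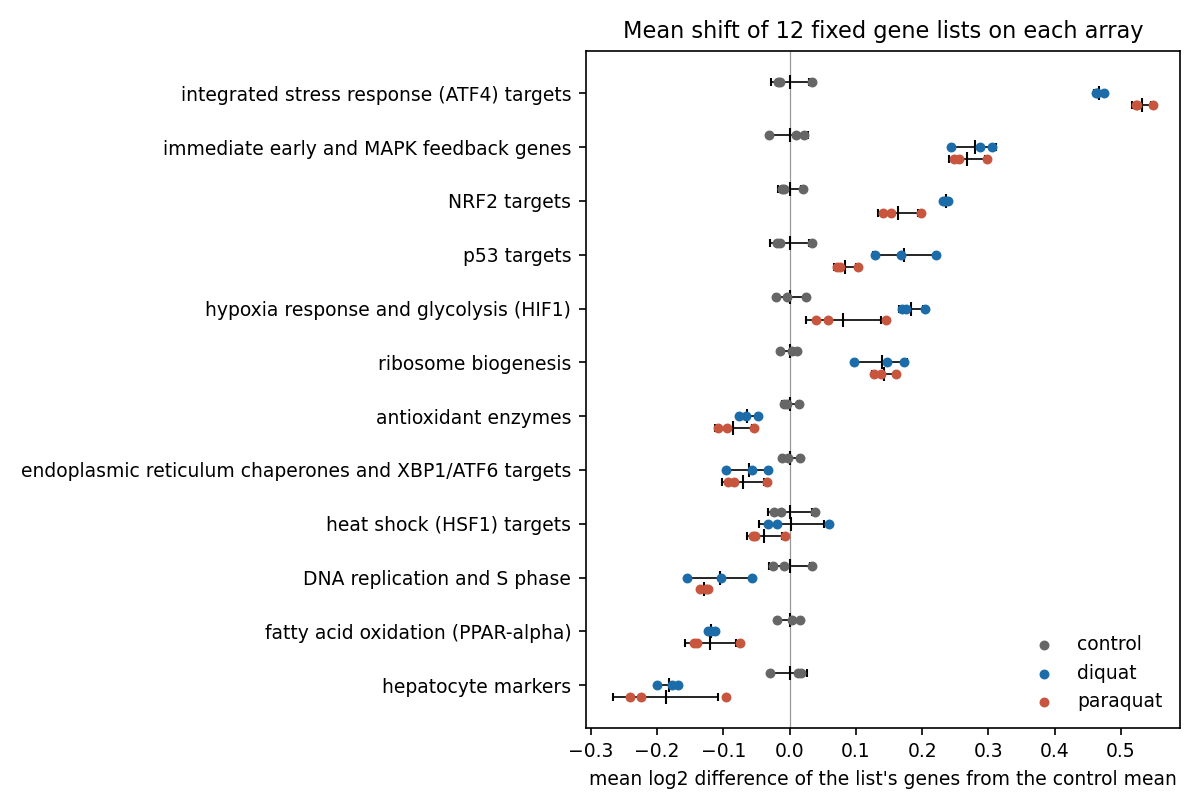
Mean log2 difference from the control mean over the genes of 12 fixed lists, for each array. Points are arrays, and black marks with whiskers are the mean and SD of 3 arrays. The ATF4 list averaged 0.47 with diquat and 0.53 with paraquat, and the hepatocyte list -0.18 and -0.19.

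Markers of other liver cell types gave no common direction. Among cholangiocyte and progenitor markers, Krt23 rose 1.79-fold with diquat and 2.09-fold with paraquat, and Sox9 1.36-fold and 1.31-fold, while Krt7 was 1.23-fold lower with diquat, and the list was not called (adjusted p = 0.109 and 0.0711). With paraquat it passed upward after centring (0.0394), with the mean of features (0.0367) and without paraquat replicate 2 or 3 (0.0436 and 0.0291). Stellate cell and fibroblast (adjusted p = 0.502 and 0.258), endothelial (0.131 and 0.559) and macrophage and leukocyte markers (0.619 and 0.434) were not called for either compound, except the endothelial list downward with diquat when diquat replicate 2 was left out (0.0177).

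The responses to the compounds were then set side by side. Of the genes called, 801 passed in the same direction in both, 444 higher and 357 lower, and 0 passed in opposite directions. The shared rises included Slc7a11, Ptgs2, Plaur, Stc1, Adm2, Creb5, Tfrc and the ATF4 targets named above, and the shared falls Slc38a4, Slc2a2, Onecut1, Txnip, Hpgd and A1cf. Independent lists of these lengths would share 21.4 higher and 14.4 lower genes. Unchanged groups set against shared controls gave at most 1 in 100 simulations, but with no effect almost no gene is called for either compound. That value therefore does not measure what shared controls add to the overlap of the genes called here. The shared count was 481 and 453 without control replicate 1 or 2, 509 and 506 without paraquat replicate 2 or 3, and 84 when tested against a fold of 1.2.

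Across genes, which are not independent replicates, the log2 fold changes of the compounds correlated with r = 0.802, against a mean of 0.499 in simulations with unchanged groups. The covariance was 0.0126 against a simulated 0.00165, a difference of 0.0109. The simulated covariance is the part that shared controls give, so the difference has it removed. With 3 control arrays, separate controls of at least 2 arrays for each compound could not be formed. Part of the excess in shared calls may therefore come from the shared controls. The r of 0.802 also holds their part, which the covariance difference leaves out.

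**Figure D3:**
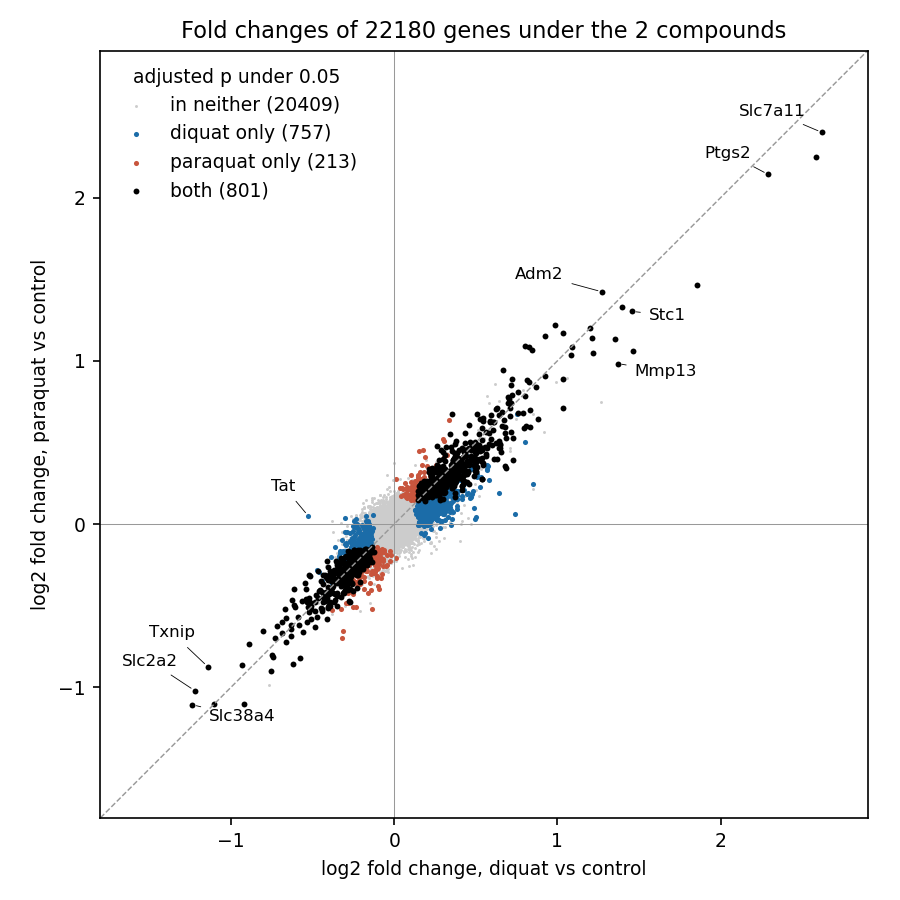
Log2 fold change of each of 22180 genes against control, diquat on the horizontal and paraquat on the vertical axis. Colours mark genes past an adjusted p of 0.05 with both compounds (801), diquat alone (757), paraquat alone (213) or neither, and the dashed line marks equal change. Points called with both compounds lie at the upper right, where both compounds raised a gene, and at the lower left, where both lowered it.

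The third comparison tested the difference between paraquat at 126 µM and diquat at 18 µM directly, at doses that differ. No gene passed limma's adjusted p, while 2371 of 22180 (10.7%) had an unadjusted p under 0.05. The smallest adjusted p, 0.0553, was shared by Tat, the tyrosine aminotransferase gene, Mllt11, Prelid2 and Mir505, of which the last 3 were chosen after their values were seen. Tat was 0.58 higher with paraquat on the log2 scale (95% interval 0.42 to 0.73): it fell 1.44-fold with diquat and changed by 0.05 with paraquat. Mllt11, Prelid2 and Mir505 were lower with paraquat by 0.34, 0.35 and 0.68 in size on the same scale. The ATF4 targets Ddit3 and Trib3 were 0.29 ± 0.04 and 0.26 ± 0.04 higher with paraquat (SE), and Txnrd1 and Slc7a11 differed by -0.21 ± 0.04 and -0.22 ± 0.08 (SE), none past the adjusted p. The 95% interval of the difference lay within 1.5-fold for 99.7% of genes and within 2-fold for 99.98%. Against control the shares were nearly as high: 98.5% with diquat and 98.8% with paraquat within 1.5-fold, and 99.74% and 99.75% within 2-fold. Genes near background were not filtered out, so these shares do not show that the compounds act alike.

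Counts past the test between the compounds depended on the setting: 4 genes (Tat, Mllt11, Prelid2 and Mir505) passed when dim genes were left out or after quantile normalization, 1 (Mir505) after median centring, 3 (Tat, Fgg and Snai2, the last chosen after its values were seen) without paraquat replicate 1 and 1 (Mir505) without paraquat replicate 2.

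Camera with the preset correlation called 7 lists between the compounds. The ATF4 list was higher with paraquat (adjusted p = 0.00178), and the p53, hypoxia, NRF2, interferon-stimulated, DNA repair and heat shock lists were lower (adjusted p = 3.39e-08, 8.04e-07, 2.38e-06, 0.000182, 0.0259 and 0.0345), with 0 members of any of them past the adjusted p over all genes. Adjusted over the list alone, 4 ATF4 targets were higher and 1 lower with paraquat, 6 hypoxia genes were lower, and the p53, NRF2, interferon-stimulated and DNA repair lists had 1 lower each and the heat shock list 0. With an estimated correlation 0 lists passed (adjusted p = 0.374 for the ATF4 list, and 0.374, 0.41, 0.374, 0.704, 0.842 and 0.789 for the others in the same order). Other splits of these 6 arrays, which keep part of any difference between the compounds, gave up to 12 lists with the preset correlation. The DNA repair call was lost without diquat replicate 1 or 3 (adjusted p = 0.0629 and 0.719) or paraquat replicate 1 or 2 (0.0701 and 0.0812), and the heat shock call without diquat replicate 3 (0.473) or paraquat replicate 2 or 3 (0.0812 and 0.0815). Both calls were also lost without dim genes (0.452 and 0.245), after quantile normalization (0.467 and 0.333), after centring (0.0609 and 0.0752) and with array weights (0.0616 and 0.148), and the heat shock call with the mean of features (0.216) and with protein-coding genes alone (0.0537). The mitochondrially encoded list, not called here, passed as higher with paraquat without diquat replicate 3 (0.0241). Test, mean and median differed in sign for the sterol, ribosome biogenesis, mitochondrial proteostasis, mitochondrially encoded, hepatocyte, cholangiocyte and stellate cell lists, none of them called.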

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

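The tests of small RNA classes and of the lists that differed between the compounds were chosen after the results were seen. The counts over other splits were planned, except those of the splits that keep the controls together.

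Features outside the gene-level comparisons, those with several gene symbols or none, also moved with treatment. Fitted on their own, 134 of 10951 such features passed limma's adjusted p for diquat against control (103 higher, 31 lower) and 97 for paraquat (78 higher, 19 lower). Between the compounds 0 passed, with 837 at an unadjusted p under 0.05. A feature annotated to U1 small nuclear RNA genes, Rnu1b1, Rnu1b2 and Rnu1b6, whose values are repeated in 9 features, was higher by 1.43 with diquat and 1.40 with paraquat on the log2 scale.

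In a wider pattern, among 8 distinct features of small RNAs transcribed from promoters of their own (U1, U3, U5, U8, U11, U12 and U13), the median log2 change was 1.11 with diquat and 0.82 with paraquat, and 6 had all treated arrays above all controls with both compounds, which argues against probes shared between copies of 1 RNA. After quantile normalization the lower of the 2 medians was 0.81. RMA had already normalized the arrays by quantiles, and array medians lay between 5.95 and 6.04. A second pass changed these medians little, from 1.11 to 1.07 with diquat and from 0.82 to 0.81 with paraquat. Over all genes it moved the share of higher calls with diquat from 58.9% to 45.2%. It repeats a step already taken, so it does not test scaling between arrays. An effect of the compounds stays open and was not tested separately. Higher recovery of small RNA from the treated dishes stays open as a possible explanation: the 7 features of small RNAs made by RNA polymerase III had a median change of at most 0.22 but went both ways, with Rny3 higher by 0.71 and 0.76 and Rny1 by 0.71 and 0.46 while Rn7sk stayed near 0, and the 78 other small nucleolar and Cajal body RNAs had medians of 0.40 and 0.24. Of those 78, 22 had all treated arrays above all controls with both compounds. The reading depends on classes chosen after the values were seen. The U5 feature, near the bottom of the range, changed by 0.07 and 0.06. Without it the lowest change in its class was 0.42 and 0.41, above the polymerase III medians. These medians cannot decide on recovery, since Rny3 and Rny1 rose by more than those lowest changes with both compounds. Telomerase RNA, a polymerase II transcript, was taken out of the polymerase III class after its values were seen, and with it those medians were 0.10 and 0.16.

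The 7 lists called between the compounds with the preset correlation were tested for an origin in diquat replicate 3 alone, the array that stood apart. Without it, 5 of the 7 passed in the same direction with the preset correlation, so those 5 preset calls did not rest on that array alone. Other splits of the 6 arrays gave up to 12 preset calls, so this does not show a difference between the compounds. With an estimated correlation 0 passed, a result known before this check was chosen. Correlated members of a list would give this, but a stricter setting can also lose a real difference, so it does not decide. The 2 compounds were tested at 1 dose each, so dose and compound cannot be told apart.

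The 6 arrays of each pair of groups have 10 splits, too few for a share under 0.05. The real split gave 1558 genes for diquat and 1014 for paraquat against control, and the highest of the other splits gave 0; with a 2-fold change the values were 22 and 24 against 0. Between the compounds all 10 splits gave 0 genes on both counts. For lists with the preset correlation, the real split gave 17, 17 and 7 for diquat against control, paraquat against control and paraquat against diquat, and the highest other split 15, 17 and 12, so that 1, 2 and 5 of 10 splits gave as many. Each of these other splits mixes the groups 2 to 1 on each side and keeps part of the difference between them, so its counts are not those of arrays without an effect. For 3 groups of 3, 1 of 100 splits, the real one, gave as many as 801 genes shared by both compounds, and the highest of the others gave 0. The correlation of 0.802 was reached by 2 of 100 splits, the real one included, with 0.816 as the highest of the others. None of the drawn splits kept the 3 controls together. The 9 other splits that do gave 693 to 829 shared genes, 1 of them as many as the real split, and correlations of 0.782 to 0.876, 8 of them as high. Among the splits tried, the shared count was therefore high only where the controls were kept together. Mixing adds the treatment difference to the spread within groups. The 0 of the mixed splits is thus not a count for arrays without an effect. The correlation separates these kinds of split less clearly, since a split that mixes controls with treated arrays reached 0.816. Neither value singles out the real assignment of compounds.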

How the results depend on the processing

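Of 105 list results, the 41 called with the preset correlation kept their direction under every alternative, while 27 of the 64 not called changed direction under at least 1. Of these, 1 also passed the test: the mitochondrially encoded list between the compounds, without diquat replicate 3 (adjusted p = 0.0241). Among the 64, 19 passed under at least 1 alternative. Higher calls were the majority for diquat as deposited (58.9%) and the minority after quantile normalization (45.2%), and for paraquat 51% and 43.9%. The fit with the replicate number as a block gave 1416 genes for diquat and 930 for paraquat against control and 0 between the compounds, with 730 shared, and changed none of these by over 1.5 times. The numbers did not clearly pair the arrays. Correlations of same-numbered deviations ran from -0.19 to 0.20, and 2 of 9 arrays correlated best with their own number. Between control and paraquat all were positive (0.16, 0.13 and 0.089), and in the other pairs of groups they went both ways.

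Counts moved by over 1.5 times in these cases. For diquat against control, 959 genes passed with the 2 groups alone and 117 against a fold of 1.2, and leaving out 1 array gave 802 to 1908 (887, 802 and 1000 without control replicate 1, 2 or 3). For paraquat, array weights gave 1623 and the fold of 1.2 gave 95, and leaving out 1 array gave 574 to 1197 (596 and 574 without control replicate 1 or 2, 575 and 574 without paraquat replicate 2 or 3). Shared genes fell to 84 against a fold of 1.2 and ran from 453 to 803 with 1 array left out (481 and 453 without control replicate 1 or 2, 509 and 506 without paraquat replicate 2 or 3). Between the compounds, 4 genes passed without dim genes, 1 after centring and 4 after quantile normalization, and 0 to 3 with 1 array left out (3 without paraquat replicate 1 and 1 without paraquat replicate 2). Testing all features gave 44 and 45 changes of at least 2-fold, where repeated features count several times. An estimated correlation left 2, 2 and 0 lists. The fold of 1.2 is a stricter null by construction; for the other alternatives the cause was not tested. With rank correlation the lowest mean correlation with group mates was 0.996 and again belonged to diquat replicate 3.

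The correlation of fold changes lay between 0.735 and 0.864 over all alternatives. Of 231 calls of named genes, 77 passed under every alternative, the fold of 1.2 included, and 0 reversed. The fit on protein-coding genes was chosen after seeing the data and gave 1629, 1089 and 0 genes. Background correction and a block for slide, strip or scan date were not run, since scanner files were not used here.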

Other observations

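The synthetase sets and the small groups of genes named here were chosen after the values were seen. The test of the NRF2 list without Slc7a11 was written before its result.

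A few genes of amino acid transport and synthesis were looked at without a test of the group. All of them but Slc1a4 belong to the ATF4 list tested above, so they add no separate evidence. The neutral amino acid exchanger Slc1a4 rose by 0.72 ± 0.05 with diquat and 0.89 ± 0.05 with paraquat on the log2 scale (limma SE), the cationic transporter Slc7a1 by 0.72 ± 0.05 and 0.74 ± 0.05, and the large neutral transporter Slc7a5 by 0.47 ± 0.04 with each. The mitochondrial folate enzyme gene Mthfd2 rose by 0.70 and 0.77 and Shmt2 by 0.27 and 0.31, while Psat1, of serine synthesis, changed by 0.09 and 0.06 and did not pass.

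Genes listed as cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, rose in 10 of 18 cases with diquat and 11 of 18 with paraquat, and fell in 0. That set holds Gars and Kars, which have no counterpart in the mitochondrial set, so the sets may not divide cleanly by compartment. Cars and Tars rose most, by 0.40 and 0.39 with diquat and 0.36 and 0.33 with paraquat on the log2 scale. Of 16 mitochondrial synthetase genes, 0 rose and 2 fell with diquat, and 1 rose and 1 fell with paraquat. Camera with an estimated correlation, which sets each set against all other genes and not against the other set, gave p = 0.00415 and 0.00288 for the cytosolic set (adjusted over the 3 sets tested, 0.0124 and 0.00864) and 0.728 and 0.935 for the mitochondrial set. The difference between the set means was 0.173 ± 0.025 with diquat and 0.161 ± 0.021 with paraquat relative to controls (SD, n = 3 each), and the lowest of the 6 treated arrays, at 0.142, lay above the 3 controls. Since the sets were picked after their values were seen on these arrays, the hypothesis that the cytosolic set rises more stays untested.

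Leaving out Slc7a11 lowered the mean log2 change of the NRF2 list from 0.235 to 0.147 with diquat and from 0.164 to 0.0815 with paraquat. Without it, 8 of 27 members rose with diquat and 6 with paraquat, and the higher of the camera p-values with the preset correlation was 0.00058, which argues against Slc7a11 as the whole cause of the preset call. With an estimated correlation p was 0.00869 with diquat and 0.0643 with paraquat (adjusted over the 3 sets tested, 0.013 and 0.0964). The full list had p = 0.00553 and 0.034 with an estimated correlation, and adjusted over 35 lists its call was lost in both (0.0646 and 0.17).

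The lowest adjusted p with either compound belonged to 2900060B14Rik, a long noncoding RNA, which rose by 2.58 ± 0.06 with diquat and 2.25 ± 0.06 with paraquat on the log2 scale (limma SE; adjusted p = 3.12e-08 and 1.24e-07). It was chosen after its values were seen.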
